A study of Populus tremula x Populus alba with 48 samples.

How the data were processed

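RNA from 4 tissues of hybrid poplar was hybridised to 48 Agilent 1-colour (Cy3) arrays. The tissues were young leaf, mature leaf, stem and root, from 2 genotypes under 3 watering conditions, which makes 24 groups of 2 arrays. Per the labels, each RNA was a pool of 5 plants, and the 2 replicates of a group came from 2 replicate experiments. Per the file headers, the authors read each array with Agilent Feature Extraction 10.5.1.1, whose processed signal is an intensity on a linear scale, background-subtracted and detrended within the array, with low values replaced by a surrogate and no scaling between arrays. The deposited value table holds the same intensity: its 43795 probes had values identical to the processed signal of the array files (largest log2 difference 0). It lacks 6 probes whose IDs start with vec_.

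Each array file lists 45218 features, of which 1417 are controls and 43801 are probes. The probes carry no gene name, description or sequence alignment in the deposited files, and no probe annotation was at hand. Probes are therefore given by ID only. The prefixes were pt_ (43665 probes), ptcp_ (85), ptmt_ (45) and vec_ (6), and the files do not say what they stand for.

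The processed signal was taken as log2, and the 75th percentile of the array's probes was subtracted, so every level given is log2 relative to that percentile. Spots that the scanner software called non-uniform or population outliers were left out (304 over all arrays, at most 73 on 1 array). No spot was saturated. A probe was tested if its signal was well above background, by the scanner software's own call, on every array of at least 1 group. This kept 25693 probes and left out 18108. Of those kept, 83 were ptcp_ probes, 31 were ptmt_ probes and 1 was a vec_ probe.

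A linear model with 24 group means was fitted to all 48 arrays in limma 3.58.1 under R 4.3.3, with the variance prior following the mean level (24 residual and 5.29 prior degrees of freedom). All tests were two-sided. Adjusted p is Benjamini-Hochberg over the 25693 probes of a comparison, with a threshold of 0.05. Numbers of shared calls are set against the number given by independent calls. All comparisons use the same fit and the same spread of a probe, so this number is not a full measure of chance. In each tissue the comparisons were the genotype in each watering condition (2 against 2 arrays), the genotype averaged over the 3 conditions (6 against 6), the drought response of each genotype (2 against 2), the difference between these drought responses (the interaction), and recovery against well-watered averaged over genotypes (4 against 4). Errors of log2 differences are the standard errors (SE) of the fit, and errors of levels are SD. The number of arrays limits the precision. Where a group was not well above background on any of its arrays, the fold is given as "at least", computed against the lowest level that the software called well above background on the same arrays, or against the probe's own level where that was higher. Such a log2 value is no measure of size. Where only some of the compared arrays were not well above background, the log2 difference is given as "at least" in the same way, and no bound is given where an array on the higher side was among them.

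The named probes follow a rule set before the data were examined: past the threshold, at least 1 log2 unit apart, with all arrays of 1 group above or below all arrays of the other in every stratum (not asked of the interaction), ranked by size. The rule also asked for a described function, which could not be applied because no probe has a description. Of the probes it took (5 per direction, or 3 for the genotype in 1 condition), at most 2 per direction are printed, those well above background in both groups first. This limit on printing was chosen after the data were seen. The probes vec_43801, pt_38698, pt_16757, pt_41232 and pt_41508 were in part followed beyond the rule, and these were chosen after their values were seen.

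The 29 gene lists fixed before the data were examined were patterns on gene descriptions, and 0 probes matched, so no list was tested and glutamine synthetase probes could not be picked out. In their place, 6 classes were chosen after the data were seen: the ptcp_ probes, the ptmt_ probes, and 4 tissue-enriched classes. A tissue-enriched probe lay at least 2 log2 units above each other tissue in the recovery arrays and was well above background on all 4 of that tissue's recovery arrays. Since recovery arrays defined them, the tissue-enriched classes were tested in comparisons without recovery arrays only. Classes were tested with camera (limma) at a preset correlation of 0.01, adjusted over 144 class tests, and again with an estimated correlation. None of the 144 passed with an estimated correlation.

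The array files place the 48 arrays on 13 slides and 6 scan days, and most comparisons lie between slides. Each count is therefore also given with slide as a random block (duplicateCorrelation with statmod 1.5.0, consensus correlation 0.314). Where the compared groups share no slide, this block cannot separate a slide difference from the difference compared, and such counts are not free of it. Slide could be fitted as a fixed term for 8 of the 32 counts. Alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, the authors' table, a separate fit per tissue, slide as a random or fixed block, the replicate number as a block, and leaving out each array in turn. Chosen after the data were seen were scan day as a random block, leaving out the drought arrays, and using wild-type arrays on 1 slide only.

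The procedure was tested on simulated data with 100 probes changed by 1 log2 unit and 100 by 2, among 25693. The simulated comparisons were those of young leaf. Noise was normal and independent between arrays, with each probe's own SD and no slide or scan-day effect. The false calls therefore do not measure the error of real comparisons that lie between slides. Real comparisons called 329 to 12378 probes, and the adjusted p depends on the share of probes that change. The recovered shares below therefore hold for the simulated setting only. For the genotype in 1 condition, 52% and 80% were recovered with 8 false calls. For the interaction, 29% and 69% were recovered with 8 false calls. For recovery against well-watered, 72% and 97% were recovered with 13 false calls. For the genotype averaged over conditions, 77% and 99% were recovered with 8 false calls.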

Results

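Transcript levels were measured in wild-type hybrid poplar and in a transgenic line that expresses a pine gene for cytosolic glutamine synthetase, the enzyme that assimilates ammonium into glutamine. The line is called GS-transgenic here. Plants of both genotypes were kept well-watered, exposed to drought, or re-watered after drought (recovery), and young leaf, mature leaf, stem and root were sampled. Per the labels, soil moisture was 50% to 55% in well-watered plants and 15% to 20% in drought, after 7 days without irrigation. Recovery plants were re-watered for 5 days after such a drought. Each of the 24 groups has 2 arrays. The 75th percentile of the probe signals ranged from 114 to 352 intensity units between arrays, and 35.6% to 55.7% of the probes were well above background. Replicate arrays correlated across probes at 0.963 to 0.993, and the median absolute difference between replicates was 0.13 to 0.31 log2 units. Levels are log2 signals relative to the 75th percentile of the array, and probes are known by ID only.

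Of the 25693 tested probes, 1 lay more than 1 log2 unit higher on every GS-transgenic array than on every wild-type array. This was vec_43801. It was well above background on all 24 arrays of the GS-transgenic line, at a level of 2.78 ± 0.48 (SD, n = 24). On the 16 well-watered and recovery arrays of wild type it was never well above background, with a measured level of -4.97 ± 0.59 (SD, n = 16). On the wild-type drought arrays it lay in between, at -1.34 ± 0.75 (SD, n = 8), and 7 of these 8 arrays were well above background. In well-watered plants the GS-transgenic level was at least 29.4-fold higher in young leaf, at least 24.5-fold in mature leaf, at least 91.9-fold in stem and at least 169-fold in root. Within 1 slide, in recovery, it was at least 48.1-fold higher in stem (adjusted p = 1.34e-15) and at least 44.3-fold higher in root (adjusted p = 5.78e-16). The files do not say what the vec_ probes target. The other 5 vec_ probes were not well above background on any array.

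**Figure D1:**
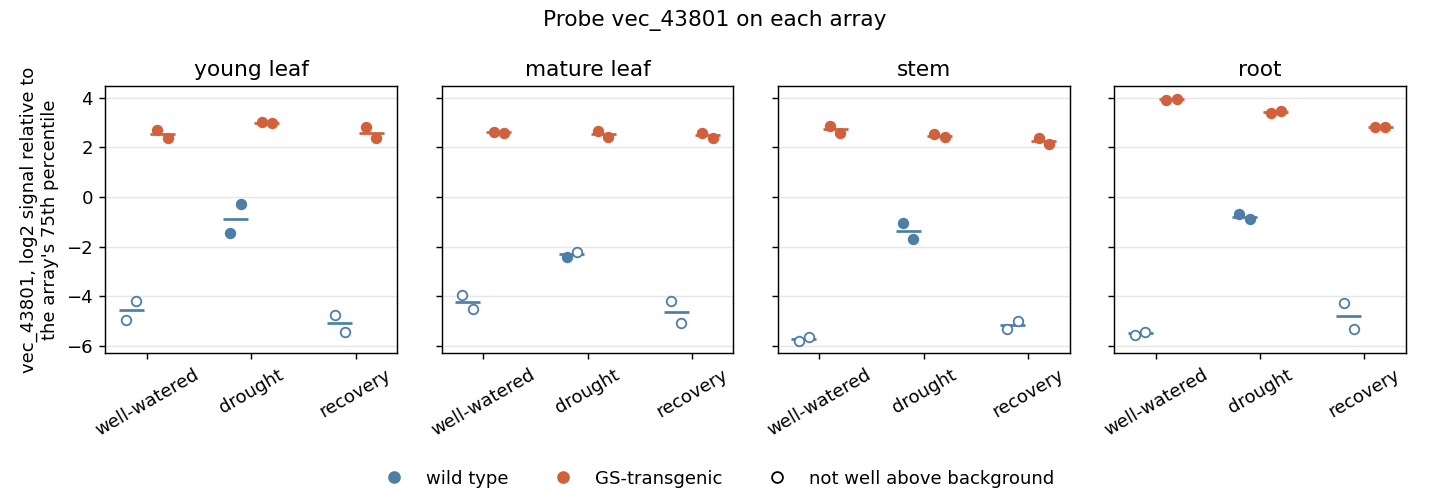
Log2 signal of probe vec_43801, relative to the 75th percentile of the array, on each of the 48 arrays, by tissue and watering condition. Open circles are arrays where the probe was not well above background. All 24 GS-transgenic arrays lie at or above 2.12, the 8 wild-type drought arrays between -2.43 and -0.28, and the 16 other wild-type arrays at or below -3.96.

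Tissues differed in the level of whole probe classes. The ptcp_ probes (83 tested) were high in leaves and lower in stem and root. Their array median was 3.08 ± 0.23 in mature leaf, 2.42 ± 0.35 in young leaf, 0.96 ± 0.45 in stem and 0.45 ± 0.42 in root (SD, n = 12 each). The lowest leaf array, at 1.74, lay above the highest stem array, at 1.66. The ptmt_ probes (31 tested) had array medians of -3.08 ± 0.22 in young leaf, -2.54 ± 0.33 in mature leaf, -2.53 ± 0.24 in stem and -2.14 ± 0.36 in root (SD, n = 12 each). In the recovery arrays, 1014 probes were enriched in root, 308 in young leaf, 211 in mature leaf and 175 in stem. These classes were chosen after the data were seen and are used for descriptions of direction below.

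**Figure D2:**
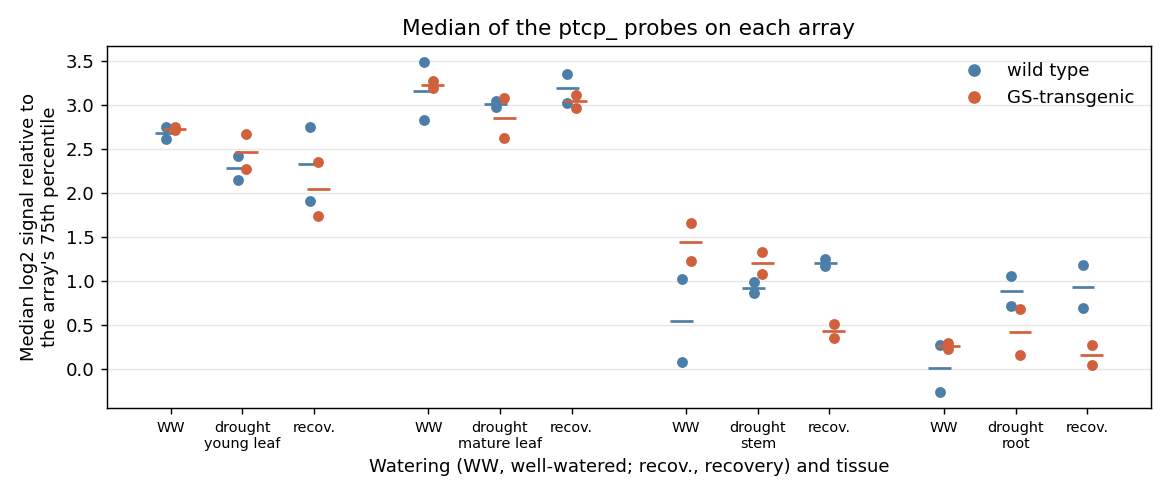
Median log2 signal of the 83 tested ptcp_ probes, relative to the 75th percentile of the array, on each of the 48 arrays, by tissue, watering condition and genotype. Leaf arrays lie between 1.74 and 3.48, stem and root arrays between -0.25 and 1.66.

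The first comparison asked how the genotypes differed when the 3 watering conditions were averaged (6 against 6 arrays per tissue). Probe pt_38698 was lower in the GS-transgenic line by at least 3.63-fold in young leaf and at least 6.13-fold in mature leaf. None of the 6 GS-transgenic arrays of either leaf was well above background, against all 6 of wild type. In mature leaf, pt_10425 was lower by 3.68 ± 0.17 log2 units (SE). In young leaf, pt_14939 was higher by 3.22 ± 0.29 log2 units (SE). In stem, pt_40436 was higher by 1.94 ± 0.29 and pt_03648 lower by 3.25 ± 0.11 log2 units (SE). In root pt_37560 was higher, and it was well above background on 5 of 6 GS-transgenic and 2 of 6 wild-type arrays, and pt_31448 was lower, with 1 of 6 against 5 of 6.

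The number of probes past the threshold was 3919 in young leaf (1812 higher and 2107 lower in the GS-transgenic line), 6338 in mature leaf (3201 and 3137), 8757 in stem (4570 and 4187) and 9295 in root (5042 and 4253). With slide as a random block these counts were 1275, 2623, 5092 and 5090, and without the drought arrays they were 4588, 5311, 4283 and 8436. The averaged conditions did not always agree. Across probes, the genotype differences in well-watered plants and in drought correlated at -0.133, 0.257, 0.679 and 0.37 (young leaf, mature leaf, stem, root). Those in well-watered plants and in recovery correlated at 0.0808, 0.471, 0.0262 and 0.255. Those in drought and in recovery correlated at 0.244, 0.371, 0.172 and -0.0776. Of the ptcp_ probes, 18 were lower and 1 higher in root (median -0.23 log2, adjusted p = 0.000399, and adjusted p = 0.981 with an estimated correlation), and 8 were lower and none higher with the slide block. In well-watered root 4 were higher and none lower (median 0.34 log2, adjusted p = 0.0013), and 1 was higher with the slide block. The array medians there were 0.30 and 0.24 in the GS-transgenic line and 0.28 and -0.25 in wild type, with the last of these arrays on a slide apart from the other root arrays. Under drought 2 were higher and 15 lower (median -0.32 log2, adjusted p = 0.000219), and none was called with the slide block. Both have adjusted p = 0.981 with an estimated correlation. Of the 31 ptmt_ probes, 6 were higher and none lower in stem (adjusted p = 0.144, and 0.981 with an estimated correlation). Across tissues, 106 probes were higher and 138 lower in all 4, where 7.88 and 6.94 would be shared if tissues were independent, which calls from 1 fit are not. The majority direction turned with the scaling in 2 tissues. In root 54.2% of the called probes were higher, and 45.6% after quantile normalization. In mature leaf 50.5% were higher, and 48.5% after normexp background correction.

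**Figure D3:**
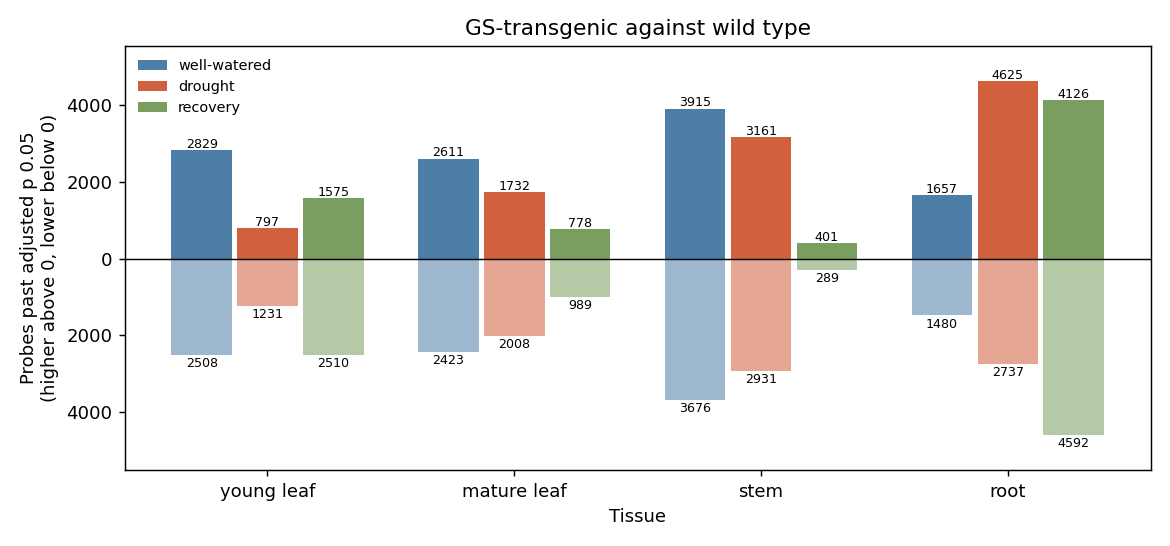
Number of probes past adjusted p 0.05 between GS-transgenic and wild type, for each tissue and watering condition, with probes higher in the GS-transgenic line above 0 and lower ones below 0. The stem has 3915 and 3676 such probes in well-watered plants and 401 and 289 in recovery.

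The genotypes were also compared within each watering condition (2 against 2 arrays). In stem many probes differed between genotypes in well-watered plants and in drought, and fewer passed the test in recovery. Probe pt_04604 was at least 54.2-fold lower in well-watered stem of the GS-transgenic line and at least 33.7-fold lower in drought. Probe pt_38291 was lower by 6.41 ± 0.59 log2 units (SE) in well-watered stem, and pt_41508 was higher by 6.46 ± 0.77 and pt_10458 higher by 5.42 ± 0.71 log2 units (SE) in stem under drought. In recovery stem, all on 1 slide, pt_04912 was lower by 4.51 ± 0.30 log2 units (SE), pt_38698 at least 3.88-fold lower and pt_06939 at least 6.85-fold higher. Among ptcp_ probes, 40 were higher and 1 lower in well-watered stem (median 0.72 log2, adjusted p = 1.68e-07), and 3 were lower and none higher in recovery stem (median -0.62 log2, adjusted p = 1.04e-17). Both have adjusted p = 0.981 with an estimated correlation. With the slide block 19 ptcp_ probes were higher and 1 lower in well-watered stem. The ptcp_ medians of the 2 wild-type arrays there were 1.02 and 0.08, the second of them on a slide apart from the other stem arrays, and those of the GS-transgenic arrays 1.23 and 1.66. Of 1014 root-enriched probes, 295 were lower and 59 higher in well-watered stem (median -0.58 log2, and -0.19 after normexp background correction, adjusted p = 2.97e-07). Of 308 young leaf-enriched probes, 91 were higher and 9 lower (median 0.68 log2, and 0.14 after normexp, adjusted p = 4.21e-05). Of 211 mature leaf-enriched probes, 48 were lower and 17 higher (median -0.41 log2, and -0.08 after normexp and after quantile normalization, adjusted p = 0.00358). Each of these 3 has adjusted p = 0.981 with an estimated correlation. Of 31 ptmt_ probes, 8 were higher and none lower there (adjusted p = 0.00233, and 0.981 with an estimated correlation).

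In recovery root all 4 arrays lay on 1 slide. Probe pt_33729 was at least 13.2-fold and pt_10030 at least 8.27-fold lower in the GS-transgenic line, and pt_28526 was at least 8.25-fold higher. Of the 83 ptcp_ probes, 38 were lower and none higher (median -0.76 log2, and -0.48 after normexp background correction, adjusted p = 3.8e-07, and 0.981 with an estimated correlation). Of the ptmt_ probes, 8 were lower and none higher (median -0.69 log2, and -0.28 after normexp, adjusted p = 0.0419, and 0.981 with an estimated correlation). In root under drought, pt_03216 was at least 18.3-fold higher and pt_00667 at least 10.2-fold lower. In well-watered root, pt_31448 was at least 4.01-fold lower. In leaves, pt_05123 was at least 12.7-fold higher in well-watered mature leaf, and pt_34191 at least 16.5-fold higher in mature leaf under drought. In young leaf, pt_43199 was at least 8.62-fold lower in well-watered plants, and pt_01156 at least 8.69-fold and pt_15951 at least 14.6-fold lower in recovery.

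In well-watered plants 5337 probes passed the threshold in young leaf (2829 higher, 2508 lower), 5034 in mature leaf (2611, 2423), 7591 in stem (3915, 3676) and 3137 in root (1657, 1480). With slide as a random block the counts were 2718, 2818, 4952 and 1300. Under drought there were 2028 in young leaf (797, 1231), 3740 in mature leaf (1732, 2008), 6092 in stem (3161, 2931) and 7362 in root (4625, 2737), and with the slide block 899, 1880, 3034 and 2757. In recovery there were 4085 in young leaf (1575, 2510), 1767 in mature leaf (778, 989), 690 in stem (401, 289) and 8718 in root (4126, 4592), and with the slide block 1139, 412, 891 and 9598. The majority direction turned with the scaling in 6 of these 12 sets. After quantile normalization the share of higher probes went from 62.8% to 44.2% in root under drought, from 52.8% to 42.8% in well-watered root, from 53.01% to 47.2% in well-watered young leaf, from 46.3% to 51.1% in mature leaf under drought and from 51.9% to 49.9% in stem under drought. After normexp background correction it went from 47.3% to 50.2% in recovery root, to 49.7% in well-watered root and to 49.3% in stem under drought. The genotypes shared a slide in recovery stem and root and lay on different slides in all other tissues and conditions, where no fixed slide term could be fitted. The difference between recovery and well-watered genotype effects was not tested.

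The drought response was the contrast of drought with well-watered plants within a genotype (2 against 2 arrays). In wild-type root, pt_34191 rose by 6.13 ± 0.73 log2 units (SE; 70.2-fold) and pt_34189 by 5.90 ± 0.59 (59.9-fold). Probe pt_38106 fell there by at least 6.87 log2 units from a level of 3.77, with 1 of the 2 drought arrays well above background, and in the GS-transgenic root at least 35.9-fold from 3.21. It stood at 5.20 ± 0.18 in wild type and 3.75 ± 0.19 in the GS-transgenic root in recovery (SD, n = 2 each). Probe pt_01925 rose at least 106-fold in GS-transgenic root, to 4.14 ± 0.28, and pt_13152 rose by 6.10 ± 0.52 log2 units (SE), while pt_01338 fell at least 39.0-fold in wild-type root and pt_00586 at least 23.4-fold in GS-transgenic root.

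Of the 83 ptcp_ probes, 51 were higher and none lower in wild-type root under drought (median 0.82 log2, adjusted p = 2.01e-12, and 0.981 with an estimated correlation), and 39 were higher with slide as a random block. The array medians were 0.72 and 1.05 in drought and 0.28 and -0.25 in well-watered wild-type root. The array at -0.25 lay on a slide apart from the other root arrays, and it also enters the difference between genotypes given below. In GS-transgenic root 10 were higher and 1 lower (median 0.23 log2, and 0.15 after normexp background correction, adjusted p = 0.37, and 0.981 with an estimated correlation). In the test of the difference between genotypes, 7 ptcp_ probes were lower and none higher (median -0.79 log2, adjusted p = 2.27e-09, and 0.981 with an estimated correlation). Of 1014 root-enriched probes, 276 fell and 18 rose in wild-type root (median -0.59 log2, adjusted p = 1.4e-10), and 285 fell and 51 rose in GS-transgenic root (median -0.44 log2, and -0.29 after normexp, adjusted p = 2.33e-08). Both have adjusted p = 0.981 with an estimated correlation. The root-enriched probes were chosen by their level in re-watered root, a choice that may favour probes lower in drought. Stem-enriched probes fell in wild-type root in 45 cases and rose in 16 (adjusted p = 0.00946, and 0.981 with an estimated correlation), and their median of -0.27 log2 was 0.00 after normexp background correction.

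Leaves and stem had other responders. In young leaf pt_05866 rose in both genotypes, at least 6.63-fold in wild type and at least 4.56-fold in the GS-transgenic line, where pt_28671 rose by 3.17 ± 0.27 log2 units (SE). Probe pt_03487 fell at least 20.4-fold in wild-type young leaf, and pt_41592 and pt_42781 fell at least 8.42-fold and at least 9.04-fold in the GS-transgenic young leaf. In mature leaf, pt_05224 rose at least 9.02-fold in wild type, and pt_27541 at least 33.4-fold in the GS-transgenic line, where pt_12989 rose by 5.23 ± 0.41 and pt_03724 fell by 5.06 ± 0.53 log2 units (SE). In that set, 90 of 308 young leaf-enriched probes were lower and 6 higher (median -0.59 log2, and -0.31 after quantile normalization, adjusted p = 2.08e-08), and 24 ptcp_ probes were lower and 2 higher (median -0.50 log2, -0.21 after quantile normalization and -0.33 after normexp, adjusted p = 4.92e-05), both with adjusted p = 0.981 with an estimated correlation. With the slide block 68 young leaf-enriched probes were lower and 5 higher, and 14 ptcp_ probes were lower and none higher. The young leaf-enriched class was dim in GS-transgenic mature leaf, with array medians of -3.99 and -3.31 (well-watered) and -4.46 and -4.53 (drought). The lowest levels called well above background on these arrays were -3.015, -2.49, -3.91 and -2.66. The class medians in wild-type mature leaf also lay below such levels, so the median changes of this class are no measure of size. In wild-type mature leaf 17 young leaf-enriched probes were higher and 7 lower (median -0.42 log2, adjusted p = 0.516). Of the ptcp_ probes, 1 was higher and 4 were lower there (median -0.18 log2, adjusted p = 0.402). In stem, pt_12463 rose by 5.35 ± 0.41 and pt_08199 fell by 3.43 ± 0.53 log2 units (SE) in the GS-transgenic line, and pt_25023 fell at least 8.89-fold in wild type. In wild type, vec_43801 rose at least 2.74-fold in young leaf, at least 5.35-fold in stem and at least 6.38-fold in root, with the call in stem lost after normexp background correction (adjusted p = 0.118). Of 211 mature leaf-enriched probes, 29 were higher and 2 lower in GS-transgenic stem (median 0.37 log2, 0.18 after quantile normalization and 0.11 after normexp, adjusted p = 4.16e-07, and 0.981 with an estimated correlation). In wild-type young leaf 49 of them were higher and 3 lower (median 0.43 log2, adjusted p = 1.4e-06, and 0.981 with an estimated correlation), but the median was -0.42 log2 after normexp background correction. With the slide block 22 were higher and 1 lower. In GS-transgenic young leaf 40 were higher and 38 lower (median -0.15 log2, and 0.32 after quantile normalization, adjusted p = 0.935). These mature leaf-enriched probes were dim in well-watered wild-type young leaf, with array medians of -3.63 and -3.07. The lowest levels called well above background there were -2.67 and -1.99. The medians of well-watered GS-transgenic young leaf also lay below such levels, so these young-leaf median changes are no measure of size.

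Drought calls in wild type numbered 2815 in young leaf (1482 higher, 1333 lower), 3316 in mature leaf (1722, 1594), 415 in stem (259, 156) and 7512 in root (4020, 3492), and with slide as a random block 941, 1498, 328 and 6928. In the GS-transgenic line they numbered 8225 in young leaf (3921, 4304), 6312 in mature leaf (3046, 3266), 1441 in stem (785, 656) and 9265 in root (5326, 3939), and with the slide block 4729, 3826, 1887 and 10105. With slide as a fixed term, 126 probes passed in wild-type stem and 5092 in wild-type root. The stem and root responses of the GS-transgenic line lie within 1 slide. The share of higher probes depended on the scaling: 52.6% in wild-type young leaf was 30.3% after normexp background correction, and in mature leaf 51.9% in wild type and 48.3% in the GS-transgenic line were 63.0% and 58.3% after quantile normalization. In the GS-transgenic line, 47.7% in young leaf was 57.1% after quantile normalization, and 57.5% in root was 49.8% after normexp. In all 4 tissues, 13 probes rose and 3 fell in wild type (0.157 and 0.0683 if tissues were independent), and 115 rose and 41 fell in the GS-transgenic line (2.94 and 2.14). Calls from 1 fit are not independent.

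**Figure D4:**
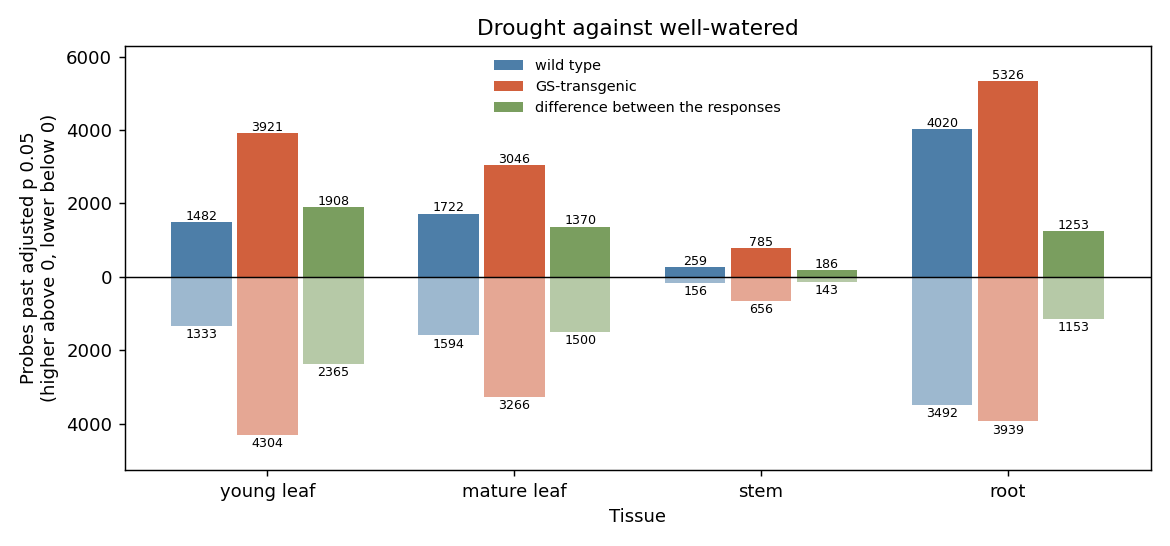
Number of probes past adjusted p 0.05 between drought and well-watered plants, for each tissue and genotype, with probes higher in drought above 0 and lower ones below 0. The root has 4020 higher and 3492 lower probes in wild type and 5326 and 3939 in the GS-transgenic line.

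Whether the genotypes responded alike to drought was tested with the interaction. In root most shared calls went the same way: 2473 probes rose and 1717 fell in both genotypes, where 833 and 535 would be shared by chance, and 244 moved in opposite directions against 1340 by chance. The log2 responses of the genotypes correlated across probes at 0.58 in root, 0.32 in mature leaf, 0.15 in stem and 0.07 in young leaf, and probes are not independent replicates. In young leaf 372 probes moved in opposite directions, against 452 by chance, 517 rose in both (226 by chance) and 629 fell in both (223 by chance). The interaction itself called 4273 probes in young leaf (1908 with the higher and 2365 with the lower response in the GS-transgenic line), 2870 in mature leaf (1370, 1500), 329 in stem (186, 143) and 2406 in root (1253, 1153). With slide as a random block it called 1321, 724, 311 and 2380, and with slide as a fixed term 160 in stem and 1618 in root. The share with the higher response in young leaf, 44.7%, was 32.3% after normexp background correction and 51.5% after quantile normalization. In stem 56.5% was 46.8% after quantile normalization, and in root 52.1% was 44.1% after quantile normalization and 46.8% after normexp.

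The probes named here were taken from the largest fitted differences in response, so they do not give the typical size, and the choice may overstate them. Of the 4273 calls in young leaf, 743 were higher and 1801 lower by at least 1 log2 unit. In stem 154 and 84 of the 329 calls were. In mature leaf, the response of pt_27650 was higher in the GS-transgenic line by at least 5.88 log2 units. In young leaf the response of pt_31006 was lower than in wild type by at least 5.77 and that of pt_28320 higher by at least 1.91 log2 units. In root the response of pt_04586 was higher by 4.21 ± 0.32 and that of pt_38029 was -5.48 ± 0.78 log2 units (SE) relative to wild type. In stem, where 329 probes passed, the response of pt_02097 was higher by at least 3.20 log2 units, and its call was lost after normexp background correction (adjusted p = 0.195).

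Recovery was compared with well-watered plants over both genotypes (4 against 4 arrays). In young leaf, pt_05866 was at least 7.58-fold and pt_32595 at least 8.34-fold higher in recovery, and pt_39471 was lower by 4.36 ± 0.56 log2 units (SE). In mature leaf pt_31832 was higher by at least 5.38 and pt_09975 by 4.05 ± 0.22 log2 units (SE), and pt_04535 was lower by at least 4.85 log2 units. In stem pt_23166 was higher by at least 4.44 log2 units and pt_30798 at least 8.04-fold lower. In root pt_36047 was higher by at least 3.67 log2 units and pt_01128 was lower by 3.73 ± 0.41 log2 units (SE). Of the 83 ptcp_ probes, 54 were lower and none higher in young leaf (median -0.65 log2, -0.39 after quantile normalization and -0.41 after normexp, adjusted p = 1.39e-07), and over both genotypes 34 were higher and none lower in root (median 0.46 log2, adjusted p = 1.19e-05). Both have adjusted p = 0.981 with an estimated correlation. In root the mean of the array medians went from 0.01 ± 0.38 in well-watered plants to 0.94 ± 0.35 in recovery in wild type, and from 0.27 ± 0.05 to 0.17 ± 0.16 in the GS-transgenic line (SD, n = 2 each), and the genotypes were not tested apart. With the slide block 52 were lower in young leaf and 16 higher in root.

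Recovery calls numbered 12378 in young leaf (5330 higher, 7048 lower), 8746 in mature leaf (4062, 4684), 8791 in stem (4092, 4699) and 10795 in root (5496, 5299), and with slide as a random block 10837, 7752, 4520 and 6424. In leaves, the wild-type arrays of these conditions lay on 1 slide per tissue, and these alone called 5730 probes in young leaf and 6014 in mature leaf. In stem and root all recovery arrays of a tissue lay on 1 slide that held no well-watered array, so no fixed slide term could be fitted there. The share of higher probes in young leaf, 43.1%, was 29.3% after normexp background correction and 55.98% after quantile normalization, and in mature leaf 46.4% was 58.5% after quantile normalization. In stem 46.5% was 51.8% after quantile normalization, and in root 50.9% was 47.5% after normexp. In all 4 tissues, 169 probes were higher and 191 lower, where 28.7 and 48.5 would be shared if tissues were independent. The tissues share the fit and the spread of each probe, so their calls are not independent.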

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

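The flagged results are differences between the genotypes in their response to drought that met the threshold of the interaction test. Of the patterns examined after them, the stem genotype difference over watering conditions and the young-leaf correlation are not calls of that test. The tests of vec_43801, the test of slides and scan days in stem, the test of slides in young leaf and the test of equal responses were chosen after the results were seen. The test of probe GC content and that of noise by the replicate correlations were set before.

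The interaction called 4273 probes in young leaf, 2870 in mature leaf, 329 in stem and 2406 in root. The fitted response in the GS-transgenic line minus that in wild type follows in log2 units, with adjusted p. Where arrays were not well above background the fitted value is no measure of size, and the bound is given beside it if there is one. In young leaf it was 3.35 for pt_28320 (0.000404, at least 1.91), 3.29 for pt_24821 (0.000262, at least 1.31), -7.49 for pt_31006 (9.72e-06, lower by at least 5.77) and -7.28 for pt_43534 (0.000795, no bound). In mature leaf it was 8.10 for pt_27650 (8.05e-08, at least 5.88), and, without a bound, 6.76 for pt_34191 (5.54e-05), -7.56 for pt_10023 (6.49e-06) and -6.56 for pt_35861 (1.19e-05). In stem it was 4.79 for pt_02097 (0.000142, at least 3.20), 4.36 for pt_10458 (0.0253), -5.53 for pt_04035 (0.000139, lower by at least 4.07) and -4.11 for pt_37507 (0.0129). In root it was 4.21 for pt_04586 (1.52e-09), 3.89 for pt_09360 (7.9e-05), -6.49 for pt_10458 (5.82e-05, lower by at least 3.20) and -5.48 for pt_38029 (1.69e-05). For vec_43801 it was -3.24 in young leaf (3.14e-05, lower by at least 1.00), -1.99 in mature leaf (0.00543, no bound), -4.61 in stem (2.01e-06, lower by at least 2.67) and -5.23 in root (1.49e-08, lower by at least 3.18).

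With normexp background correction the calls of pt_43534 in young leaf (-1.39, adjusted p = 0.142), pt_02097 (1.22, 0.195) and pt_04035 (-1.47, 0.212) in stem and pt_10458 in root (-1.73, 0.0715) were lost. With slide as a fixed term those of pt_10458 (4.26, 0.0821) and pt_37507 (-3.25, 0.124) in stem were lost. Leaving out 1 array ended the stem call of pt_10458 for each of 5 arrays (adjusted p 0.0682 to 0.195) and that of pt_37507 for each of 4 (0.0586 to 0.136). Among these was replicate 1 of the well-watered GS-transgenic stem, without which the values were 3.05 and -4.04.

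The first pattern is the signal of vec_43801 on wild-type drought arrays, at 5.83% ± 2.44 (SD, n = 8) of the level in the GS-transgenic line under drought. Signal carried between arrays of 1 slide is argued against, because wild-type stem and root drought arrays, on slides without GS-transgenic arrays, lay 3.90 log2 units above wild-type recovery arrays that shared a slide with them (-1.09 ± 0.43 against -4.98 ± 0.50, SD, n = 4 each). RNA of GS-transgenic plants under drought mixed into the samples may be the source: every abundant probe should then lie at or above its share, and the largest shortfall was 2.61 ± 0.84 log2 units (SE) in stem (pt_41508, measured 2.20 where 4.81 was needed) and 1.26 ± 0.80 in the other 3 tissues (pt_34191 in mature leaf). Neither passed a bound of 4 SE that was set after the levels were seen, so mixing stays open, and a count of probes below the bound, 0 in each tissue, was replaced by this shortfall after its first run. A wild-type drought transcript that the probe also detects stays open as the biological explanation, since the GS-transgenic level changed by a mean of -0.0935 log2 units from well-watered to drought over the 4 tissues (SE 0.33 in each), too coarse to see a rise of that size.

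The second pattern is the genotype difference in stem, with 7591 calls in well-watered plants, 6092 in drought and 690 in recovery. A trend with probe GC content is argued against, since 7571 probes were called in well-watered plants without and 7042 with its removal from each array, 5954 of them in both and in the same direction (suspect spots kept). A difference between slides or scan days could also give the pattern: across probes the well-watered genotype difference correlated at 0.68 with that in drought, on the same slides but for 1 of the 4 well-watered arrays, and at 0.026 with that in recovery, within 1 slide. The layout keeps this open, because in well-watered plants and in drought the genotypes lay on different slides in stem. A genotype difference that depends on the watering condition is the biological explanation, and it stays open as well.

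The third pattern is the low correlation across probes of the young-leaf drought responses of the 2 genotypes, 0.07. Noise between replicates was to be set aside if the replicate responses correlated at 0.4 or more in both genotypes, and the lower value, in wild type, was 0.3996, just short of that, with 0.69 in the GS-transgenic line. With the arrays paired the other way the wild-type value was 0.132, so equal responses with noise alone would need a correlation of 0.302 or more between single drought differences of the genotypes, and the 16 such correlations ran from -0.321 to 0.383, on both sides of it. Slides that differ between well-watered and drought arrays could also add to it: with slide as a random block the interaction called 1321 probes in place of 4273. Neither explanation is settled in young leaf by these values, and a different drought response of the genotypes stays open there. The test of equal responses was also run in the other tissues. In stem the 16 correlations ran from -0.0211 to 0.22, below the 0.393 needed, which argues against noise between replicates alone in stem. In mature leaf (-0.0496 to 0.502, 0.259 needed) and root (0.287 to 0.648, 0.562 needed) they lay on both sides.

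For the genotype averaged over conditions, splits of the arrays within watering conditions were counted in each tissue, with suspect spots kept. In young leaf the real split gave 3904 calls and the highest other split 3404, in mature leaf 6319 and 4600, in stem 8707 and 8147, and in root 9251 and 8250. Only 1 of 100 splits, the real one, gave as many in each tissue. Splits that put arrays of both genotypes in 1 group take genotype or slide differences into the spread, which lowers their counts. The splits therefore show only that arrays were not exchangeable between genotypes. They do not separate genotype from slide or give the number of true differences. For recovery against well-watered, 18 splits within genotypes are too few for a share under 0.05. The real split gave 12334, 8716, 8776 and 10765 calls in young leaf, mature leaf, stem and root, and the highest other split 6947, 2884, 4634 and 4377.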

How the results depend on the processing

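Scan day as a block, leaving out the drought arrays and using wild-type arrays on 1 slide were chosen after the data were seen, and the other alternatives before. Where 4 counts are given they stand for young leaf, mature leaf, stem and root. Apart from the left-out arrays and the replicate block, every count given below moved by over 1.5 times, and the cause was not tested. Of the 32 counts, quantile normalization and the authors' table moved 0, normexp background correction 29, slide as a random block 22, scan day as a random block 21, a fit within the tissue 9 and no filter 3. The authors' table holds the values of the main fit without the vec_ probes, so its result was fixed in advance and is no test. Of the 8 counts that slide as a fixed term could give, 2 moved. Signal over background limits the dim probes, since 35.6% to 55.7% of the probes were well above background on an array. None of the named probes' values changed direction under any of these settings.

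The replicate numbers were not taken as pairs. Same-numbered arrays of the 15 pairs of groups per tissue had median correlations of their deviations of -0.00, -0.04, -0.02 and 0.01, and 3, 6, 3 and 3 of the 15 were over 0.1. The single correlations ran from -0.287 to 0.364, -0.287 to 0.69, -0.125 to 0.196 and -0.19 to 0.193. Spike-in controls were higher in replicate 1 than in replicate 2 in 21 of 24 groups, by a mean of 0.81 log2 units, which is a hint from the data that a number marks something the arrays share. With the replicate number as a block, 0 of the 32 counts moved by over 1.5 times (5422 in young leaf for the genotype in well-watered plants). The alternatives for the 29 gene lists were not run, because 0 probes matched a list. Slide as a fixed term could not be fitted for the other 24 counts.

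With normexp background correction the counts were 3307, 1747, 4302 and 863 for the genotype in well-watered plants, and 865, 2004, 3515 and 2169 for the genotype in drought. They were 2273, 640, 371 and 5380 for the genotype in recovery, and 1037 in mature leaf, 183 in stem and 4141 in root for drought in wild type. Counts were 4014, 3053, 580 and 4803 for drought in the GS-transgenic line, and 1522, 855, 104 and 692 for the interaction. There were 5107 in mature leaf and 7074 in root for recovery, and 2345, 2980, 5348 and 4800 for the averaged genotype.

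With slide as a random block (correlation 0.314) they were 2718, 2818, 4952 and 1300 for the genotype in well-watered plants, and 899, 1880, 3034 and 2757 for the genotype in drought. They were 1139 in young leaf and 412 in mature leaf for the genotype in recovery, and 941 in young leaf and 1498 in mature leaf for drought in wild type. Counts were 4729 in young leaf and 3826 in mature leaf for drought in the GS-transgenic line, and 1321 in young leaf and 724 in mature leaf for the interaction. There were 4520 in stem and 6424 in root for recovery, and 1275, 2623, 5092 and 5090 for the averaged genotype.

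With scan day as a random block (correlation 0.348) they were 1941, 2386, 4737 and 1114 for the genotype in well-watered plants, and 812, 2439, 2724 and 2352 for the genotype in drought. They were 1224 in young leaf and 619 in mature leaf for the genotype in recovery, and 660 in young leaf and 1134 in mature leaf for drought in wild type. Counts were 4574 in young leaf for drought in the GS-transgenic line, and 605 in young leaf and 720 in mature leaf for the interaction. There were 4117 in stem and 5883 in root for recovery, and 1303, 2996, 4713 and 4592 for the averaged genotype.

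Slide as a fixed term gave 126 in stem for drought in wild type, and 160 in stem for the interaction. A fit within the tissue gave 1225 in root for the genotype in well-watered plants, and 1294 in young leaf and 3992 in root for the genotype in drought, and 1662 in stem for the genotype in recovery. They were 1785 in young leaf and 1324 in stem for drought in wild type, and 2953 in stem for drought in the GS-transgenic line, and 1044 in stem and 989 in root for the interaction. With no filter counts were 19348 in root for the genotype in drought, and 212 in stem for the interaction, and 27091 in young leaf for recovery. Of these, 16252 were higher and 3096 lower in root for the genotype in drought (84% higher, against 62.8% with the filter), and 5499 higher and 21592 lower in young leaf for recovery (20.3% against 43.1%). The majority direction turned without the filter in mature leaf (49% higher) and stem (48.1%) for the genotype in well-watered plants, mature leaf (49.2%) for drought in wild type, root (49.5%) for the interaction, stem (51.3%) for recovery, and mature leaf (48.4%) and stem (49.8%) for the averaged genotype. Without the drought arrays the count was 4283 in stem for the averaged genotype. Wild type within 1 slide gave 5730 in young leaf for recovery, of which 54% were higher.

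Leaving out 1 array left its group with 1 array, assumed to vary like the other groups. The lowest and highest counts follow, with the genotype, condition and replicate of the array left out (WT, wild type; GS, GS-transgenic). The genotype in well-watered plants ranged in young leaf 3182 (GS well-watered 2) to 3865 (WT well-watered 2), mature leaf 2860 (WT well-watered 1) to 4304 (GS well-watered 1), stem 4546 (GS well-watered 2) to 6273 (WT well-watered 1) and root 1571 (GS well-watered 1) to 2536 (WT well-watered 2). The genotype in drought ranged in young leaf 554 (WT drought 2) to 2965 (WT drought 1), mature leaf 1990 (GS drought 2) to 3415 (WT drought 1), stem 3529 (WT drought 2) to 4024 (WT drought 1) and root 3260 (GS drought 2) to 5980 (WT drought 2). The genotype in recovery ranged in young leaf 1174 (WT recovery 2) to 3087 (WT recovery 1), mature leaf 455 (GS recovery 1) to 1069 (WT recovery 1), stem 238 (GS recovery 2) to 450 (WT recovery 2) and root 6136 (GS recovery 1) to 6848 (GS recovery 2). Drought in wild type ranged in young leaf 1282 (WT well-watered 2) to 2172 (WT drought 2), mature leaf 1840 (WT well-watered 1) to 4423 (WT drought 2), stem 96 (WT well-watered 2) to 663 (WT well-watered 1) and root 3737 (WT drought 2) to 7846 (WT well-watered 1). Drought in the GS-transgenic line ranged in young leaf 5195 (GS well-watered 2) to 6147 (GS well-watered 1), mature leaf 3369 (GS drought 1) to 5600 (GS well-watered 1), stem 397 (GS well-watered 1) to 686 (GS drought 2) and root 6386 (GS well-watered 1) to 8274 (GS well-watered 2). The interaction ranged in young leaf 1992 (WT drought 2) to 5425 (WT drought 1), mature leaf 1694 (GS well-watered 2) to 3222 (GS well-watered 1), stem 81 (GS drought 1) to 372 (WT well-watered 1) and root 1291 (GS well-watered 1) to 3873 (WT well-watered 1). Recovery ranged in young leaf 9735 (WT well-watered 2) to 12042 (WT well-watered 1), mature leaf 6875 (WT recovery 2) to 8277 (GS well-watered 1), stem 7066 (WT well-watered 2) to 8415 (WT well-watered 1) and root 8947 (WT well-watered 1) to 10694 (WT well-watered 2). The averaged genotype ranged in young leaf 3039 (WT recovery 2) to 4225 (WT drought 1), mature leaf 5137 (GS recovery 1) to 7284 (WT drought 1), stem 7430 (GS recovery 2) to 8065 (WT well-watered 1) and root 7660 (GS drought 2) to 9592 (WT well-watered 2).

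Among the values of the rule's named probes, a call was lost 18 times when 1 array was left out (counted per array), 10 times with normexp background correction, 2 with a fit within the tissue, 2 with slide as a fixed term, 2 with scan day and 1 with slide as a random block, and 1 without the drought arrays. pt_16757 in young leaf under drought went from 4.35 to 2.50 log2 units (adjusted p = 0.299) without GS drought replicate 2, and pt_31708 in root, averaged, to -2.04 (adjusted p = 0.0807) without WT well-watered replicate 1.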

Other observations

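The levels of pt_38698 are described here beyond its printed comparisons, and it was chosen after its values were seen, as was the comparison of control spots. In wild type pt_38698 was well above background on all 6 arrays of young leaf, mature leaf and stem, at levels of -1.15 ± 0.31, -0.43 ± 0.26 and -1.86 ± 0.26 (SD, n = 6 each). In root it was well above background on 4 of 6 wild-type arrays, with none of the 2 recovery arrays among them. In the GS-transgenic line it was well above background on 1 of 24 arrays, a stem array under drought. In wild type its drought response passed the threshold in no tissue. A drought response of this probe could not be measured in the GS-transgenic line at these levels.

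Drought responses were shared between tissues to different degrees. In the GS-transgenic line, 407 probes rose and 353 fell in both young leaf and stem, where 120 and 110 would be shared by chance, and 25 moved in opposite directions against 232 by chance. In wild type, 1164 probes called in both young leaf and root moved in opposite directions, where 410 would by chance, and 150 rose and 57 fell in both. In mature leaf and young leaf of wild type, 423 probes rose and 255 fell in both, against 99.3 and 82.7 by chance. Calls in 2 tissues come from the same fit, and the leaf responses lie between slides.

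The 5 brightest spike-in controls, which are added to the RNA before labelling, had mean log2 levels relative to the 75th percentile of 4.51 ± 0.89 in well-watered, 4.42 ± 0.58 in drought and 3.10 ± 0.97 in recovery arrays (SD, n = 16 each). Recovery minus well-watered was -1.41 (two-sided permutation p = 0.00159, 100000 resamples within tissue and genotype), and recovery was lower in 7 of 8 combinations of tissue and genotype. The permutation exchanges arrays across replicate numbers, though the controls were higher in replicate 1 in 21 of 24 groups. It also takes arrays as exchangeable across slides, but recovery and well-watered arrays shared a slide only in wild-type leaves. There the differences were -0.23 in young leaf and -0.54 in mature leaf. Between slides they were -0.74 in stem and 0.44 in root of wild type, and -3.08 in young leaf, -3.34 in mature leaf, -2.21 in stem and -1.60 in root of the GS-transgenic line. The genotypes were not tested apart.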
